A study of Mus musculus with 6 samples.

How the data were processed

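Poly(A) RNA from E14 mouse embryonic stem cells was sequenced in 6 libraries, 3 from sucrose cushion pellets and 3 from resin eluates, with groups taken from the sample titles. Per the labels' protocols, cells were given cycloheximide before harvest, and the material of each cushion was divided between direct RNA extraction and the resin. Per the submitters' processing notes, cutadapt 4.7, STAR 2.7.11b, Salmon 1.10.3 and DESeq2 1.44.0 were used with genome build GRCm39, with no role or order given. The annotation release and the settings of these tools are not given in the sources used here. Per the file headers, each library's deposited file holds the authors' Salmon output per transcript, with an estimated count, TPM (abundance scaled to the same total in each library), a length and an effective length. The authors' deposited table of the comparison holds, per the file headers, mean normalized counts, log2 fold changes with standard errors, a Wald statistic as a score, and p-values with adjusted p-values, for genes with an adjusted p under 0.05. Its design formula is not given in the sources used here.

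The 84226 transcripts were matched by identifier to GENCODE mouse release 21, used for names, gene classes, lengths and GC content. That release uses another genome build, so no coordinates are printed. The match took 76858 transcripts of 51912 genes, 75250 of them with the same length. The other 7368 transcripts held 1.63% to 2.35% of a library's estimated counts and were left out of the gene tests. Some genes are therefore counted from part of their transcripts. Near-identical transcripts can exchange reads in such estimates, so genes with paralogs, pseudogenes or nuclear copies are uncertain. Library totals were 7.84e+06 to 1.16e+07 estimated counts. Chi-square values per gene between libraries of a group were 3.12 to 18.0, and between groups 32.9 to 82.0, so no library was counted as a repeat of another.

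Estimated counts were summed per gene, rounded to whole numbers and tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood fit with robust dispersion, TMM factors, the default low-count filter, Benjamini-Hochberg adjustment, adjusted p under 0.05). The 95% intervals for the 1.5-fold bound came from limma 3.58.1 (voom). Gene lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. DESeq2 1.42.0 served as an alternative. Shares of counts by gene class were compared by a two-sided exact permutation test, and rank relations with length by an exact sign-flip test over the 3 replicate numbers. Tables and plots used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

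On data simulated for the eluate and pellet comparison, with 13231 genes in the step and 50 changed at each size, the edgeR test recovered 56% of genes changed 1.5-fold, 78% at 2-fold, 96% at 3-fold and 90% at 4-fold, and 10 of 192 calls (5.21%) were false. A further 40 genes were raised by 0.5 on the log2 scale as 1 list, and 22 of them were called, which are among the 192. Each gene was drawn on its own there, with no shift shared by the genes of a library. The share of false calls therefore need not hold for the real libraries. Genes were named by a rule fixed before the data were examined. It took the 5 highest and 5 lowest fold changes among called genes with a mean CPM of at least 10 and the same sign for all 3 replicate numbers, leaving out unnamed and provisional symbols. In each list it took the member with the smallest p, the member with the highest mean CPM and the member with the smallest p in the other direction. The 20 lists were fixed at the same time. Other names are said to be chosen after their values were seen.

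Alternatives fixed before the data were examined were other scaling factors, other count filters, a replicate block, leaving out each library and each pair of libraries with the same number, an effective-length offset, leaving out mitochondrial genes, other tests and thresholds, transcript-level tests, TPM in place of counts, and other length measures. Alternatives chosen after seeing the data were the removal of each library's smooth trend in GC and length (splines with 5 degrees of freedom), removal of the GC trend alone, the block with the GC and length trend removed, adding nuclear copies to the mitochondrial genes they match, keeping unmatched transcripts, leaving out genes with 3 counts or fewer over a group, and the relation with length after GC.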

Results

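Poly(A) RNA was sequenced from E14 cells, a line of mouse embryonic stem cells, at 2 steps of a ribosome purification named RAPIDASH. Lysates of cells given cycloheximide, which holds ribosomes on their messages, were spun through a sucrose cushion, and each ribosome-containing pellet was divided, with a part extracted directly and a part put through chromatography on a resin charged with cysteine. The labels number the samples of each kind 1 to 3 without saying that a number marks parts of the same pellet. The 6 libraries were 3 cushion pellets and 3 resin eluates. The libraries held 8.44e+06, 1.04e+07 and 7.84e+06 estimated read counts in pellets 1 to 3 and 1.16e+07, 1.13e+07 and 1.002e+07 in eluates 1 to 3. The design asks which messages the resin step enriches or depletes relative to the cushion alone. The labels name the samples as replicates without saying that they came from separate cultures, so p-values measure the spread between these samples. Log CPM values correlated across genes at 0.978 to 0.987 within a group and at 0.940 to 0.967 between groups, and no pair of libraries was near-identical. Pellet 1 lay between the other pellets and the eluates on the first principal component, at -19.1 against -42.9 and -45.3 for pellets 2 and 3 and 30.4 to 41.8 for the eluates.

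Compared with the pellets, the eluates held less of many messages with long coding sequences, Smc2, Mki67 and Aspm among them, and less of the mitochondrially encoded messages, and more of many short GC-rich messages. Throughout, changes are log2 fold changes of eluate over pellet ± SE and CPM values are means ± SD, from 3 libraries per group, with adjusted p from edgeR's quasi-likelihood test. The SE was derived from that test, as the absolute change divided by the square root of its F statistic. Smc2, a condensin subunit, fell by 2.32 on the log2 scale (SE 0.31; 20.4 ± 3.01 CPM in the eluates and 102 ± 31.9 in the pellets; adjusted p = 0.00255). Mki67, the proliferation antigen Ki-67, changed by -2.26 ± 0.43, with an adjusted p of 0.0622 without both libraries numbered 3, and Aspm, a spindle pole protein, by -2.23 ± 0.24. Of the next lowest genes with counts in both groups, chosen after their values were seen, the zinc finger gene Zfp292 changed by -2.21 ± 0.28 and Top2b, topoisomerase II beta, by -2.20 ± 0.20. Chchd10, a mitochondrial protein gene, rose by 1.06 ± 0.078 (892 ± 43.0 CPM in the eluates and 427 ± 46.2 in the pellets; adjusted p = 9.71e-08). Pcsk1n, which encodes a proprotein convertase inhibitor, rose by 1.25 ± 0.11, Fam89b by 1.27 ± 0.16 and the linker histone gene H1fx by 1.55 ± 0.099. With the GC and length trend of each library removed, a fit chosen after the data were seen, these changes kept their direction and were smaller: -1.22 for Smc2, -1.19 for Aspm, -0.87 for Zfp292, -0.97 for Top2b, 0.28 for Chchd10, 0.87 for Pcsk1n, 0.55 for Fam89b and 0.67 for H1fx. Mki67 was at -1.39 there and no longer called (adjusted p = 0.0645).

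Exosc6, an RNA exosome subunit, had the highest fold change at 4.34 ± 0.98 (adjusted p = 0.0218), but it was listed at 0 CPM in pellets 2 and 3, at 5.25 CPM in pellet 1 and at 33.6, 39.3 and 33.7 CPM in the eluates. It stayed called without pellet 2 (adjusted p = 0.0495) and without pellet 1 (adjusted p = 4.17e-27), where the pellets left are both at 0 and no fold is given. Its adjusted p was 0.0562 without pellet 3, 0.0688, 0.0758 and 0.069 without eluates 1, 2 and 3, 0.16 and 0.148 without both libraries numbered 2 and 3, and 0.123 with DESeq2, so the call did not hold in these settings. The size of its change is uncertain too, at 7.08 with limma voom (adjusted p = 0.000174) and 9.07 in the authors' deposited table (adjusted p = 0.00156). With the replicate number as a block, edgeR gave 4.45 and no call (adjusted p = 0.107). DESeq2 with that block gave 9.11 and called the gene (adjusted p = 0.00138). Zdbf2 and Snx14 were listed at 0 counts in every eluate among the transcripts that could be matched to them, at 33.5 ± 2.46 and 22.4 ± 3.21 CPM in the pellets, and no fold is given for them. In the authors' deposited table their log2 fold changes are -1.82 and -1.32, so the zeros are no finding about these genes. In all, 6 genes had 3 counts or fewer over a whole group, and all 6 were called. The matched transcripts of Zdbf2, Snx14 and H1fx held 0.605, 0.722 and 0.471 times the counts that the authors' deposited table gives for the gene, and for H1fx that table has a log2 fold change of 1.19, below its 1.22 for Fam89b.

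Over all 13231 genes tested, 3241 were higher and 3736 lower in the eluates at an adjusted p under 0.05, which is 52.7% of the genes. Large changes were mostly decreases: 1143 of the called genes were lower and 110 higher by at least 1 on the log2 scale. The median log2 fold change was 0.0035, with 10th and 90th percentiles of -0.96 and 0.58. For 60.3% of the genes every eluate lay on the same side of every pellet, where chance gives 10%. The 95% interval of limma voom lay within 1.5-fold either way for 4833 genes (36.5%) and wholly beyond 1.5-fold for 1497. Without both libraries of replicate number 3, 4611 genes were called and 883 lay wholly beyond 1.5-fold. In the fit with the GC and length trend removed, 4562 genes were called. Of the 6977 genes called here, 3164 were called in that fit too and 2691 of them in the same direction. In that fit 7736 genes lay within 1.5-fold and 316 wholly beyond it. Of 54 genes named here, all called and above 3 counts in both groups, 36 kept their direction there with a change over 1.5 times smaller, 10 kept it within 1.5 times and 8 turned, and 18 of the 54 were no longer called.

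Messages rich in A and T and messages with long coding sequences were lower in the eluates. In 10 equal groups of genes ordered by GC content, the median log2 fold change went from -0.94 at a median GC of 40.4% to 0.49 at 60.2%. In the first of these groups 79.5% of the genes were lower and 1.21% higher, and in the last 0.605% were lower and 60.6% higher. Spearman's rho across genes between fold change and GC was 0.71 overall and 0.56, 0.70 and 0.68 for the libraries numbered 1, 2 and 3. For transcript length, the relation fixed in advance, rho was -0.44 overall and -0.48, -0.39 and -0.38 by number, with an exact two-sided sign-flip p of 0.25, the smallest that 3 pairs allow. Across the 12220 nuclear genes with a coding sequence, the median went from 0.30 at a coding length of 378 nt to -0.52 at 4386 nt. Genes are not independent replicates, and the relations with GC and with coding length had the same sign-flip p of 0.25. GC also differed within a group: the difference of pellet 1 from the other pellets had a rho of 0.592 with GC across genes.

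**Figure D1:**
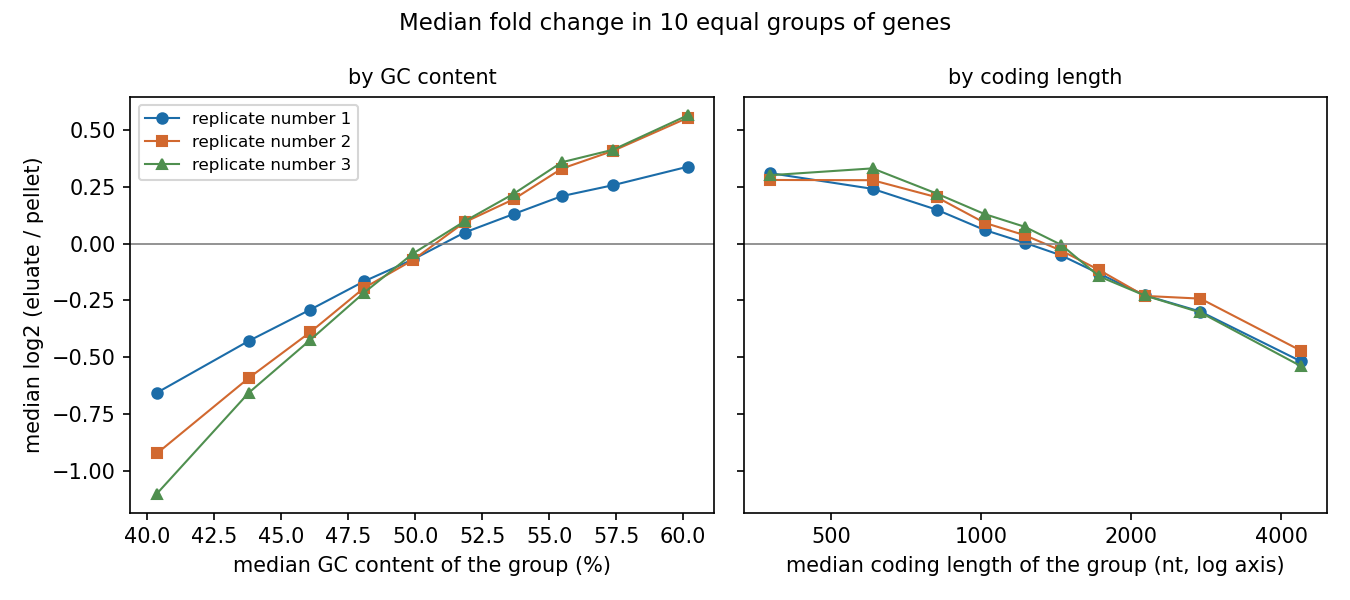
Median log2 ratio of eluate to pellet (y axis) in 10 equal groups of tested genes ordered by GC content (left, percent) or coding length (right, nucleotides, log axis), with a line for each replicate number. With rising GC the medians go from -0.66, -0.92 and -1.10 to 0.34, 0.55 and 0.56, and with rising coding length from 0.31, 0.28 and 0.30 to -0.52, -0.47 and -0.54.

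Mitochondrially encoded messages were lower in the eluates as a group. Of the 13 messages, 12 fell, and the same 12 were lower adjusted over the list alone, with a median of -1.54 (camera adjusted p = 2.18e-05; adjusted p = 0.51 with an estimated correlation). mt-Co1, cytochrome oxidase subunit 1, changed by -1.45 ± 0.25 (7477 ± 939.7 CPM in the eluates and 20418 ± 5378 in the pellets; adjusted p = 0.00795), and mt-Nd2, a complex I subunit, by -1.54 ± 0.24. Without both libraries numbered 2 the adjusted p of mt-Co1 was 0.105. The mitochondrial ribosomal RNAs changed by -0.96 ± 0.29 for mt-Rnr1 and -1.91 ± 0.43 for mt-Rnr2. The member that did not pass was mt-Nd3, at 0.08 ± 0.36 (adjusted p = 0.882). mt-Nd3, mt-Atp6, mt-Co2 and mt-Co3 each have a nuclear copy, Gm28438, Gm10925, Gm28661 and Gm28437, that holds at least 98.1% of their 31-base subsequences, and reads can be split between the copies. With the copies added to their messages, an alternative chosen after the data were seen, all 13 messages fell, from -2.11 for mt-Atp8 to -1.004 for mt-Co3, and mt-Nd3 changed by -1.08 ± 0.27 (adjusted p = 0.0265). Mitochondrially encoded genes took 4.36%, 6.56% and 7.20% of the matched counts in pellets 1 to 3 and 2.21%, 2.58% and 2.67% in the eluates (6.04% ± 1.49 and 2.48% ± 0.240, SD, n = 3 each, exact permutation p = 0.1, the smallest that 3 against 3 allows). Reads assigned to the nuclear copies are not in these shares. Without the trend in GC and length the median of the 13 was -0.73, with 10 lower (adjusted p = 1.33e-06; adjusted p = 0.573 with an estimated correlation).

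**Figure D2:**
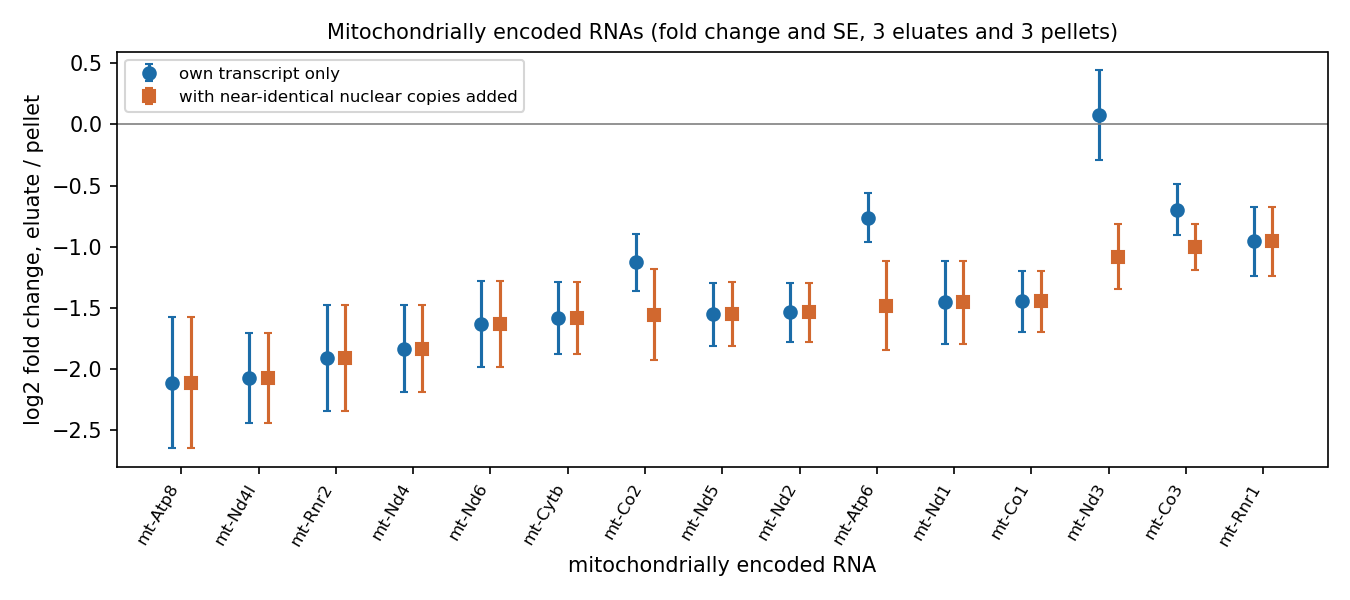
Log2 fold change of eluate over pellet (y axis; point and SE, 3 libraries per group) for the 13 mitochondrially encoded messages and 2 ribosomal RNAs (x axis), counted by their own transcript (circles) or with near-identical nuclear copies added (squares). All squares lie below 0, while the circle of mt-Nd3 is at 0.08.

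Messages for ribosomal proteins and for the nuclear-encoded parts of mitochondria were higher in the eluates. Of 79 cytosolic ribosomal protein genes, 53 rose, 3 fell and 23 did not pass, with the same counts adjusted over the list alone (median 0.29; camera adjusted p = 2.06e-11; adjusted p = 0.51 with an estimated correlation). Rplp2, a stalk protein, rose by 0.80 ± 0.068 (adjusted p = 2.99e-07), Rpl5 fell by 0.41, Rpl4 and Rpl7, named after their values were seen, fell by 0.35 and 0.22, and Rps2, the most abundant, was at 0.04 ± 0.061 (adjusted p = 0.565; 6972 ± 171 CPM in the eluates and 6759 ± 245 in the pellets). Together the ribosomal protein genes took 14.5% ± 0.215 of matched counts in the pellets and 17.6% ± 0.245 in the eluates. Of 78 mitochondrial ribosomal protein genes, 55 rose and 4 fell (Mrpl1 and, named after their values were seen, Mrps22, Mrpl47 and Mrps9), also adjusted over the list alone (median 0.34; adjusted p = 1.38e-09; adjusted p = 0.43 with an estimated correlation). Mrps34 rose by 0.77 ± 0.076, the abundant Mrpl12 by 0.34 ± 0.060, and Mrpl1 fell by 0.91. Of 76 nuclear oxidative phosphorylation genes, 52 rose, 3 fell and 21 did not pass, with 53 higher and 3 lower adjusted over the list alone (median 0.33; adjusted p = 2.06e-11; adjusted p = 0.43 with an estimated correlation). Atp5g2, a subunit of the ATP synthase ring, rose by 0.84 ± 0.066, while Ndufs1, the largest complex I subunit, fell by 1.29. Sdha and Uqcrc2, named after their values were seen, fell by 0.77 and 0.42, and Atp5b, the most abundant, had a log2 fold change of -0.03 ± 0.065.

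With the GC and length trend of each library removed, the ribosomal protein genes turned to a median of -0.12, with 18 higher and 34 lower (adjusted p = 0.080). There Rps2 was lower at -0.55, Mrpl12 lower at -0.19 and Rpl5 at 0.11 (adjusted p = 0.0928), and Mrps34 and Mrpl1 were no longer called at 0.01 and -0.14. The mitochondrial ribosomal protein genes kept their direction (median 0.09; adjusted p = 0.00259; adjusted p = 0.573 with an estimated correlation), and the oxidative phosphorylation genes no longer passed (median 0.06; adjusted p = 0.241), while Atp5b was lower and called at -0.20. With GC alone removed the 3 lists stayed higher and called (adjusted p = 9.94e-10 for ribosomal proteins, 2.69e-14 for mitochondrial ribosomal proteins and 5.11e-12 for oxidative phosphorylation; 0.512, 0.45 and 0.45 with an estimated correlation), so the calls that ended did so once length was removed as well. Counts of ribosomal protein genes, Eef1a1 and Gapdh are uncertain where reads can also come from processed pseudogenes, a class that held 1.40% ± 0.018 of matched counts in the pellets and 1.47% ± 0.018 in the eluates.

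**Figure D3:**
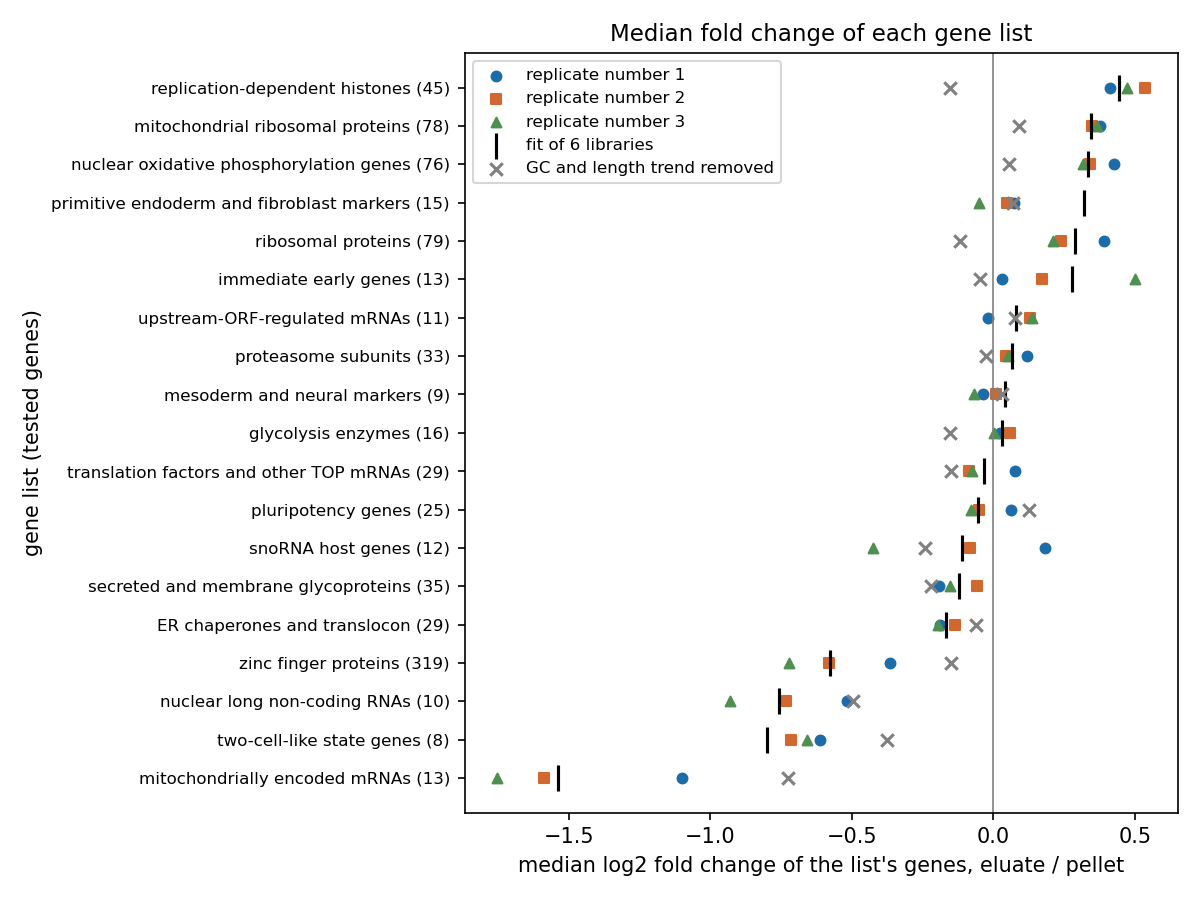
Median log2 fold change of eluate over pellet (x axis) of each gene list with at least 3 tested genes (y axis, tested genes in brackets), for the ratio of libraries of each replicate number (circles, squares, triangles), the fit of all 6 libraries (bars) and that fit with the GC and length trend removed (crosses). Mitochondrially encoded messages have the lowest median of the fit, -1.54, and replication-dependent histones the highest, 0.44, which is -0.15 with the trend removed.

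Translation factors and other messages with a 5' terminal oligopyrimidine tract went both ways. Of 29 genes, 10 rose, 13 fell and 6 did not pass, with 11 higher and 13 lower adjusted over the list alone (median -0.03; adjusted p = 0.758). With the trend removed the list was lower, with 5 higher and 15 lower (median -0.15; adjusted p = 0.0365; adjusted p = 0.618 with an estimated correlation). Eif3f, a subunit of initiation factor 3, rose by 0.74 ± 0.064 (adjusted p = 3.23e-07), and Eif2s3x, a subunit of initiation factor 2, fell by 0.95. The elongation factor gene Eef1a1, the most abundant of the list, was at -0.03 ± 0.062 (adjusted p = 0.717; 12708 ± 273 CPM in the eluates and 12968 ± 619.9 in the pellets), and at 0.25 and called with GC alone removed. Among 11 messages regulated by upstream open reading frames, 4 rose and 5 fell, the same adjusted over the list alone (adjusted p = 0.829). Ppp1r15a, a stress-induced phosphatase subunit, rose by 0.53 ± 0.084, Eif5 fell by 0.65, and Atf4 was at 0.08 ± 0.064 (adjusted p = 0.301). Eif5 with the trend removed was at 0.08 and Atf4 was lower at -0.26.

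Non-coding RNAs that act in the nucleus were lower in the eluates. Of 10 tested, 9 fell and Pvt1 did not pass, the same adjusted over the list alone (median -0.76; adjusted p = 0.00479; adjusted p = 0.51 with an estimated correlation). Malat1, a nuclear speckle RNA, changed by -1.63 ± 0.16 (adjusted p = 7.88e-07; 5.56 ± 1.01 CPM in the eluates and 17.4 ± 0.700 in the pellets), and Rian, from the imprinted Dlk1-Dio3 region, by -0.75 ± 0.093. The matched transcripts of Malat1 and Rian held 0.185 and 0.336 times the counts of the authors' deposited table, where their log2 fold changes are -1.67 and -0.79. With the trend removed the list stayed lower (median -0.50; adjusted p = 0.028; adjusted p = 0.573 with an estimated correlation). Replication-dependent histone messages, most of which lack a poly(A) tail, had 12 members higher, 0 lower and 33 not called of 45, and 7 higher adjusted over the list alone (median 0.44; adjusted p = 0.00479; adjusted p = 0.43 with an estimated correlation). Hist1h2bc rose by 0.75 ± 0.14 and Hist1h2bk by 0.79 ± 0.17, at 17.1 ± 3.41 CPM in the eluates and 9.90 ± 1.77 in the pellets. With the trend removed the histone median was -0.15 (adjusted p = 0.855) and Hist1h2bk was at 0.084, not called, and with GC alone removed the list was not called either (adjusted p = 0.246). Of 12 snoRNA host genes, Snhg1 fell by 0.36 and Snhg18 rose by 1.22 ± 0.41 at 0.759 and 1.74 CPM in pellets and eluates, with Snhg1 alone lower adjusted over the list alone (adjusted p of the list = 0.724). The call of Snhg18 was lost without pellet 1 or 2 or eluate 1 or 3 (adjusted p = 0.0722, 0.0851, 0.0522 and 0.0859), without both libraries numbered 1 or 2 (0.0896 and 0.0857) and with DESeq2 (0.109), and that of Snhg1 without both libraries numbered 2 or 3 (adjusted p = 0.0624 and 0.114). With the trend removed Snhg1 was at 0.031, and the host gene list was lower, with 1 higher and 6 lower (median -0.24; adjusted p = 0.0365; adjusted p = 0.573 with an estimated correlation). Among small structured RNAs of other particles, Rn7s2, a 7SL RNA gene, was the member with enough counts to test, at -2.13 ± 1.56 (adjusted p = 0.322). Its adjusted p was 0.0366 without pellet 2 and 0.00351 without both libraries numbered 2. With the replicate number as a block it was 0.0109, and 0.00189 with the GC and length trend removed as well. Rn7s2 was listed at 2.80, 0 and 5.34 CPM in pellets 1 to 3 and at 1.31, 0 and 0.40 CPM in eluates 1 to 3. These values rest on 64 counts over the pellets and 19 over the eluates, too few to take it as depleted.

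Messages translated at the endoplasmic reticulum also went both ways. Of 29 genes for its chaperones and translocon, 8 rose, 13 fell and 8 did not pass, with the same counts adjusted over the list alone (median -0.17; adjusted p = 0.246). Hspa5, the chaperone BiP, fell by 0.99 (204 ± 10.7 CPM in the eluates and 408 ± 22.9 in the pellets; adjusted p = 5.86e-08), and Ssr2, a translocon-associated subunit, rose by 0.55 ± 0.061. Of 35 genes for secreted and membrane glycoproteins, 9 rose and 16 fell, with 10 higher and 16 lower adjusted over the list alone (median -0.12; adjusted p = 0.0954). Tfrc, the transferrin receptor, fell by 1.69 (SE 0.10), Bsg, basigin, rose by 0.67 ± 0.063, and the apolipoprotein gene Apoe by 0.63 ± 0.078. With the trend removed Hspa5 and Tfrc stayed lower, at -0.72 and -0.66, Apoe was at -0.10 (adjusted p = 0.172), and Ssr2 was no longer called at 0.072. The glycoprotein list was lower there (median -0.22; adjusted p = 0.0114; adjusted p = 0.573 with an estimated correlation) and with GC alone removed (adjusted p = 0.000133; adjusted p = 0.45 with an estimated correlation), and it also passed without pellet 2 (adjusted p = 0.0304) and without eluate 1 (adjusted p = 0.050).

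Genes named Zfp and a number, most of which encode zinc finger transcription factors, were lower in the eluates. Of 319 tested, 179 fell, 39 rose and 101 did not pass, with 43 higher and 183 lower adjusted over the list alone (median -0.57; adjusted p = 1.03e-05; adjusted p = 0.51 with an estimated correlation). Zfp871 fell by 1.63, Zfp42, the pluripotency factor Rex1, by 0.21 (706 CPM in the eluates and 817 in the pellets), and Zfp428 rose by 0.91 ± 0.085. The call of Zfp42 was lost without pellet 2 or 3 or eluate 1 or 3 (adjusted p = 0.112, 0.0702, 0.053 and 0.127) and without both libraries numbered 2 or 3 (0.171 and 0.257). With the trend removed the list was at -0.15 (adjusted p = 0.0645) and Zfp871, Zfp42 and Zfp428 were not called, while with GC alone removed the list stayed lower and called (adjusted p = 0.00866; adjusted p = 0.45 with an estimated correlation) and Zfp42 was higher at 0.15. Of 33 proteasome genes, 14 rose, 8 fell and 11 did not pass, the same adjusted over the list alone (adjusted p = 0.300). With GC alone removed the proteasome list was higher (adjusted p = 0.00115; adjusted p = 0.45 with an estimated correlation). Psmd1, a scaffold of the regulatory particle, fell by 1.14 (SE 0.068; adjusted p = 2.81e-08), while the core subunit genes Psmb2 and Psmb4 rose by 0.73 ± 0.070 and 0.34 ± 0.060. Psmd1 stayed lower at -0.80 with the trend removed, and Psmb4 was at -0.025. Of 16 glycolysis genes, 4 rose and 2 fell, the same adjusted over the list alone (adjusted p = 0.425). Hk2, hexokinase 2, fell by 0.85 and Gapdh rose by 0.54 ± 0.066. The glycolysis list was lower with the trend removed (median -0.15; adjusted p = 0.028; adjusted p = 0.573 with an estimated correlation) and Gapdh was at 0.01.

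Camera called none of the 3 lists of genes that mark the state of the cells in the fit of all 6 libraries, while fry called the pluripotency genes (adjusted p = 0.0217, up) and those of the 2-cell-like state (adjusted p = 0.00308, down). Of 25 pluripotency genes, 12 rose, 7 fell and 6 did not pass, also adjusted over the list alone; the median was -0.05 while the mean, 0.029, and the test pointed up (adjusted p = 0.425). Utf1, a chromatin-bound transcription factor, rose by 0.99 ± 0.069 (724 ± 12.3 CPM in the eluates and 366 ± 29.6 in the pellets; adjusted p = 7.29e-08), Dppa5a by 0.52 ± 0.062, and Tfcp2l1 fell by 0.56. Tfcp2l1 was higher, at 0.22, with the trend removed. Of 8 genes of the 2-cell-like state, which resembles the early embryo, 5 fell and 0 rose, the same adjusted over the list alone (median -0.80; adjusted p = 0.0746), with Zscan4f at -1.04 ± 0.18 and Zscan4c at -1.01 ± 0.18. With GC alone removed Zscan4c was at -0.32 and no longer called (adjusted p = 0.104). The Zscan4 genes are near-identical copies whose reads can be split. Of 13 immediate early genes, 4 rose and Klf6 fell by 0.84, with 3 higher and Klf6 lower adjusted over the list alone (adjusted p = 0.0954); Jund rose by 0.91 ± 0.12 and Ier2 by 0.45 ± 0.11. The list passed without pellet 1 (adjusted p = 0.0373), without both libraries numbered 1 (adjusted p = 0.046) and with no count filter (adjusted p = 0.0498). The adjusted p of Ier2 was 0.050 without both libraries numbered 3. Ier2 with the trend removed was lower, at -0.21, and Jund and Klf6 were no longer called.

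Markers of other cell types went both ways. Of 15 primitive endoderm and fibroblast markers tested, 3 rose (Thy1 and, named after their values were seen, Amn and Sox17) and 3 fell (Lama1 and, named likewise, Cubn and Fbn1), with 2 higher and 3 lower adjusted over the list alone (adjusted p = 0.829). Lama1, a laminin chain and the most abundant, fell by 0.61 (37.5 ± 1.84 CPM in the eluates and 57.2 ± 4.39 in the pellets) and Thy1 rose by 0.70 ± 0.15. The adjusted p of Thy1 was 0.0637 without both libraries numbered 3 and 0.166 with the trend removed. Of 9 mesoderm and neural markers tested, Ncam1 and, named after their values were seen, Nes and Map2 fell and Gsc rose, the same adjusted over the list alone; the median was 0.04 while the mean, -0.17, and the test pointed down (adjusted p = 0.76). Ncam1 changed by -0.84 ± 0.13, Gsc by 0.89 ± 0.32 at 1.19 and 2.22 CPM in pellets and eluates, with the call lost without pellet 2 or 3 or eluate 2 or 3 (adjusted p = 0.0871, 0.0846, 0.0788 and 0.064), without both libraries numbered 2 or 3 (0.165 and 0.141), with DESeq2 (0.152), with no count filter (0.0508) and with an effective-length offset (0.0589), and at 0.030 with the trend removed, and Tubb3 was at 0.08 ± 0.092 (adjusted p = 0.512; -0.40 and called with the trend removed).

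Camera called 7 of the 19 lists with at least 3 tested members, 4 higher and 3 lower in the eluates, at a preset correlation between genes. None of the 7 held with an estimated correlation, where the smallest adjusted p was 0.43. The number of lists called was not particular to the real grouping: 6 of the 10 splits of the samples, the real one included, gave as many. Fry, which asks whether the genes of a list move together without comparing them with other genes, called 12: these 7, the pluripotency genes, higher, and the endoplasmic reticulum, glycoprotein, 2-cell-like and mesoderm and neural lists, lower. With the GC and length trend removed, 7 lists were called, 3 of them in common with the fit as reported, and none of the 7 held with an estimated correlation, where the smallest adjusted p was 0.573. The 3 in common were the mitochondrially encoded messages and nuclear non-coding RNAs, both lower, and the mitochondrial ribosomal proteins, higher. With GC alone removed 8 lists were called: those called in the fit as reported other than the histones, and the glycoprotein and proteasome lists. None of these held with an estimated correlation either, where the smallest adjusted p was 0.45.

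By gene class, 11 of 13 classes had every eluate on one side of every pellet, each with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allows (adjusted p = 0.118 over the 13 classes). Protein-coding genes took 96.1% ± 0.657 of the matched counts in the pellets and 97.1% ± 0.027 in the eluates (SD, n = 3 each). Mitochondrial ribosomal RNA took 0.103% ± 0.038 and 0.0374% ± 0.0036. Unprocessed pseudogenes took 1.19% ± 0.623 in the pellets and 0.251% ± 0.014 in the eluates, with 0.529% in pellet 1 against 1.76% and 1.29% in pellets 2 and 3, and their 4 most abundant members were the nuclear copies of mt-Atp6, mt-Co2, mt-Co3 and mt-Nd3. These copies were at 4610, 3652, 3102 and 656 CPM in the pellets and 734, 579, 807 and 246 CPM in the eluates. Their reads may come from the mitochondrial messages, which count as protein-coding. The differences of the unprocessed pseudogene and protein-coding classes are therefore not separate findings. Antisense RNAs took 0.315% ± 0.0076 and 0.288% ± 0.0097, and lincRNAs, long intergenic non-coding RNAs, 0.276% ± 0.0032 and 0.257% ± 0.0032. As shares of TPM, lincRNAs were at 0.485% in the pellets and 0.503% in the eluates, the opposite order.

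The authors' deposited table lists 4892 genes, all with an adjusted p under 0.05, of which 2177 are higher and 2715 lower in the eluate, and 45 and 877 by at least 1 on the log2 scale. Of these, 4849 were tested here. Of the 4849, 4773 were called and 4844 had the same sign, with a Spearman's rho of 0.992 between the log2 fold changes. These values cover only genes that passed the authors' threshold. Of the 6977 genes called here, 4773 are in the authors' deposited table and the rest are not. The fit here had no replicate block, and the design formula of that table is not given in the sources used here. For Hspa5 the authors' deposited table gives -0.96 where -0.99 was found here, for Psmd1 -1.10 where -1.14 was found, and for Chchd10 1.02 where 1.06 was found. The matched counts of 57 of the authors' genes tested here (1.18%) differed from the table's mean counts, with the larger over 25% above the smaller. Both come from the same libraries, so the overlap is no independent evidence.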

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

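Of the 7368 transcripts that were not matched to a gene and were left out of the gene tests, 477 had enough counts to test, and 40 of them were higher and 76 lower in the eluates, with 361 not called and a median log2 fold change of -0.11. They are given here because they lie outside the gene-level comparison. No explanation of these values was tested.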

How the results depend on the processing

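The calls of 6977 genes, 3241 higher and 3736 lower, stayed within 1.5 times under other scaling factors (6967 and 6770), other count filters, DESeq2 (5946) and limma voom (6885). Leaving out single libraries or both libraries of a number gave 4611 to 7761 calls, 1949 to 3722 higher and 2662 to 4039 lower, 7 to 8 lists, 3679 to 4479 genes within 1.5-fold and 883 to 2062 beyond it, 4118 to 4777 genes shared with the authors' deposited table, Spearman correlations of -0.46 to -0.39 with length and 0.66 to 0.73 with GC, and, for both libraries of a number alone, 11 to 12 classes apart. The values of 4611, 1949 and 883 came without both libraries numbered 3. Against a 1.5-fold change 1420 genes were called (176 higher, 1244 lower, 1365 in the authors' table), and with a log2 change of at least 1 there were 1253 (110, 1143 and 1038), by the stricter criterion. The Spearman correlation of fold change was -0.21 with length and 0.45 with GC with no count filter, and with length -0.49 at a mean count of at least 50 and -0.51 at a mean CPM of at least 10; the cause was not tested. An estimated correlation left 0 lists and fry called 12.

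The removals of trends in GC and length were chosen after seeing the data. With both removed 4562 genes were called (2316 lower), 2554 of them in the authors' table, with 7736 genes within 1.5-fold and 316 beyond it. Of the calls reported, 3164 were made there and 2691 in the same direction. Among genes and lists called in at least 1 of the 2 fits, direction turned for Rps2 (-0.55), Rpl5 (0.11), Mrpl12 (-0.19), Snhg1 (0.031), Apoe (-0.095), Eif5 (0.077), Atf4 (-0.26), Tfcp2l1 (0.22), Tubb3 (-0.40), Ier2 (-0.21) and Psmb4 (-0.025), and for the ribosomal protein, histone and glycolysis lists (adjusted p = 0.080, 0.855 and 0.028). The lists of translation factors and snoRNA host genes gained a call as lower (adjusted p = 0.0365 each). Over 1.5 times smaller in the same direction were, beside those given in the report, Rplp2 (0.23), Atp5g2 (0.21), Eif2s3x (-0.35), Ppp1r15a (0.19), Rian (-0.26), Bsg (0.14), Psmb2 (0.40), Utf1 (0.17), Dppa5a (0.30), Zscan4f (-0.67), Zscan4c (-0.43), Lama1 (-0.27), Ncam1 (-0.48), mt-Co1 (-0.79) and mt-Nd2 (-0.73). With GC alone removed 3082 of the calls were in the authors' table, and Rps2 (-0.29), Rpl5 (0.26), Eef1a1 (0.25), Snhg1 (0.36), Eif5 (0.077), Atf4 (-0.14), Zfp42 (0.15), Tubb3 (-0.32) and Ier2 (-0.074) turned. By construction these fits remove any difference that follows GC or length, technical or not. With TPM in place of counts, an alternative fixed in advance, the eluate minus pellet shares turned to 0.000569 percentage points for RNAs from bidirectional promoters, 0.0187 for lincRNAs and -0.00794 for the annotation class TEC (0.000522 by counts, within its spread), and moved to 2.76 for protein-coding genes, -2.67 for unprocessed pseudogenes, -0.102 for antisense RNAs, -5.26 for mitochondrially encoded genes and 4.65 for ribosomal protein genes; the cause was not tested. Over all settings, 31 of 1601 values of named genes turned, 96 lost and 6 gained a call, and of 436 list values 6 turned, 12 lost and 18 gained a call. Every one of these turns came in a fit with the GC trend, or the GC and length trend, removed.

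With the replicate number as a block, 7076 genes were called (3306 higher, 3770 lower) and 7 lists. Of the named genes, Exosc6 was not called (adjusted p = 0.107) and Rn7s2 was (adjusted p = 0.0109), from 64 counts over the pellets and 19 over the eluates. Samples of the same number had deviations from their group means that correlated at 0.0698, 0.151 and -0.0102, and pellets 1 and 3 and eluate 3 did not correlate best with their own number, so the numbers were not taken to pair the samples. With 3 libraries per group these correlations cannot exclude pairing. Standard errors of the authors' deposited table lay nearer to DESeq2 with the block (median ratio 0.950) than without it (1.155). The sign-flip tests and SDs over replicate numbers do set libraries of the same number against each other. DESeq2 called 4934 genes with the block and 5946 without it, and the authors' deposited table lists 4892. For Exosc6 DESeq2 gave 9.11 with the block and 4.36 without it, and that table gives 9.07. By these values too, the table lay nearer to the fit with the block. With the block and the GC and length trend removed, 4552 genes were called (2306 lower), 2563 of them in the authors' table, and the same named genes turned as without the block: Rps2 (-0.55), Rpl5 (0.11), Mrpl12 (-0.19), Snhg1 (0.024), Apoe (-0.096), Eif5 (0.077), Atf4 (-0.26), Tfcp2l1 (0.22), Tubb3 (-0.40), Ier2 (-0.21) and Psmb4 (-0.025). The ribosomal protein, histone and glycolysis lists turned as well (adjusted p = 0.0612, 0.710 and 0.0248), and the lists of translation factors and snoRNA host genes were again lower (adjusted p = 0.0369 each).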

Other observations

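Groups of genes that were not among the lists fixed in advance were also lower in the eluates. They were written down after the most changed genes had been seen, and several members were picked for their change, so their p-values are no independent evidence. Of 19 subunits of condensin, cohesin and the SMC5/6 complex, which shape chromosomes, 14 fell and 3 rose, with a median log2 fold change of -1.35. Ncapg changed by -2.08 ± 0.13 and Smc4 by -1.65 ± 0.32 (SE, n = 3 per group), while Nsmce1 rose by 0.35 ± 0.075. Of 48 ribosome biogenesis factors 30 fell and 10 rose (median -0.60), with Nop58, a core protein of snoRNA particles, at -1.51 ± 0.21. Of 20 cytosolic aminoacyl-tRNA synthetases 10 fell and 2 rose (median -0.18), with Eprs at -1.48 ± 0.091. With the GC and length trend removed 14, 30 and 14 members fell and 3, 9 and 0 rose (camera adjusted p = 6.36e-06, 9.76e-07 and 1.7e-05; adjusted p = 0.229 for each with an estimated correlation).

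In what follows, the tests of the mitochondrial messages and of coding length were chosen after the results were seen; those of GC and of the splits of the samples were fixed before. The rise of fold change with GC was tested against selection by coding sequence or translation, which would need a slope among long non-coding genes under 0.5 times that of coding genes. The ratio was 0.797 (SD 0.028 over 3 replicate numbers, 510 non-coding genes), which argues against such selection as the whole cause. A bias in GC acting on fragments would give non-coding genes a slope too, so the test cannot exclude a contribution. A GC bias acting on fragments during library preparation or sequencing would need the GC of the 3' UTR to count as that of the coding part does. The ratio of the slopes was 0.606 (SD 0.0047, 7551 genes), inside the range set for it but below 1, so such a bias may account for at least part of the trend. With the authors' effective lengths as an offset, whose ratio of eluate to pellet follows GC (rho 0.798), the relation of fold change with GC was 0.66 against 0.71 (SD 0.0747 over replicate numbers). Genes wholly beyond 1.5-fold were 1289 with the offset against 1497, and those within 1.5-fold 5113 against 4833. Whether those lengths model GC is not given in the sources used here. GC also separated pellet 1 from the other pellets (rho 0.592), and a selection of messages by the resin that follows GC stays open, untested.

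The fall of the mitochondrially encoded messages was compared with nuclear coding genes of like GC and length. Matched to the 20 nearest genes each, with nuclear copies added, the 13 messages were lower by a median of -1.05 (SD 0.202), where GC and length alone would leave a difference within 0.25. An earlier matching used a window of 2 GC points and 1.5-fold in length, with messages counted by their own transcripts. It covered 8 of the 13 messages and gave -0.897 (SD 0.12), and it was replaced to cover all 13. Both argue against GC and transcript length as the whole cause. Coding length was not matched, although mt-Co1, for example, is almost wholly coding (1542 of 1545 nt). The 20 nearest genes were also higher in GC, by a median of 1.39 percentage points. Whole mitochondria or mitochondrial ribosomes held back at the resin step would lower the 13 messages and 2 ribosomal RNAs alike, but with each of the 15 taken against their mean in the same library, the spread of the fold changes was 2.69 times its standard error (2.07 to 3.16 with 1 library left out); a first form, not taken against that mean, gave an SD of 0.349 beside a median SE of 0.34, but that SE also holds the shift between libraries that the members share, so it decides nothing. The log2 ratio of mt-Rnr2 to mt-Rnr1 was 0.74 ± 0.25 in the pellets and -0.16 ± 0.078 in the eluates (SD, n = 3 each). The values argue against a joint loss as the whole cause, and a joint loss of part stays open. The trend of each library in GC and length was left in for this comparison. That trend could spread the members too, so a joint loss beside it is not excluded.

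The fall with coding length was tested against RNA breakage before poly(A) selection, which would act on 3' UTR length as on coding length. The slope per kb of 3' UTR was 0.0116 times that of coding sequence (SD 0.052, 8519 genes), which argues against breakage as the whole cause. The rank relation with 3' UTR length after GC was weak but negative, at -0.10 in the fit of all libraries and -0.17, -0.073 and -0.041 by number. A part for breakage is therefore not excluded. The GC content of long messages was tested by the rank relation with coding length after GC, which was -0.540 (SD 0.021, mean over the 3 replicate numbers), also against it as the whole cause. A step that follows the number of ribosomes on a message, or the size of the complex, may contribute and was not tested.

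The 6 samples can be split into groups of 3 in 10 ways, too few for a share of splits under 0.05. The real split called 6977 genes and the highest of the others 0, so 1 of the 10 splits gave as many. For lists the real split called 7 and the highest other 7, with 6 of the 10 splits giving as many. The number of lists called was therefore not particular to the real split. Every other split has an unequal mix of eluates and pellets on each side, so it may hold part of the same difference. For genes wholly beyond 1.5-fold the values were 1497 and 17, with 1 of the 10 splits as large.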
